A study of Drosophila melanogaster with 3 samples.

How the data were processed

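The series comprised 2 ORC2 ChIP samples and 1 input DNA sample of S2-DRSC cells. Chromatin was cross-linked, extracted and precipitated, and libraries were made for Illumina sequencing, per the labels' protocols. A list of peaks was used for each ORC2 sample, together with 1 list of the whole series. Reads and signal tracks, and the input sample itself, were not used here.

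Per the file headers, coordinates are those of FlyBase release 5. Each peak carries the name of the caller, PeakSeq, which compares ChIP reads with control reads, and a score, which the authors deposited without saying what it is relative to. The aligner, the caller's version and threshold and the control used are not given in the sources used here. Peak names carry the replicate number in the lists of the samples, so these were called per sample. The whole-series list was checked against them. All 4230 of its peaks spanned the outer edges of touching peaks of both replicates, and in 4115 of 4115 cases with 1 peak from each replicate its score was their mean within 1e-05. In the other 115 cases more than 1 peak of a replicate was merged. Scores are the authors' own. They were used to describe, rank and filter peaks, to compare shared with unshared peaks and chromosomes within a list, and to compare the replicates where peaks overlapped. No counts, and so no depth per sample, are given in the lists. Intervals on shares of peaks are exact binomial and cover the counting of peaks only.

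Overlap meant at least 1 bp in common. It was tested against 1000 circular shifts of the replicate 2 list along each sequence, which keep the number, widths and spacing of its peaks (one-sided permutation test). Alternatives were an overlap of at least 50% of both peaks, centres within 500 bp, the 50% of each list with the highest scores, the large arms only (2L, 2R, 3L, 3R and X), and uniform placement. Lengths of the sequences were taken as the last base of any peak on them, since no genome of release 5 was used here. Density on the X was compared with 2L, 2R, 3L and 3R over windows of 100 kb by a two-sided permutation of windows with 100000 resamples, with an interval from 2000 bootstrap draws of windows; 50 kb and 500 kb windows, percent of bases covered, the 50% of peaks with the highest scores and each replicate alone were alternatives. Spacing was tested against 1000 uniform placements within each arm (two-sided). Correlations of scores used peaks that overlapped one to one, with intervals from 1000 bootstrap draws of peaks. Median scores of shared and unshared peaks were compared by two-sided permutation tests with 100000 resamples, and those of the X and the autosome arms in the closing section with 10000. The threshold was 0.05.

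Which samples, tests, alternatives and named regions to use was fixed before the data were examined. For files without a matching annotation, the rule named the 12 whole-series peaks with the highest score on the large arms and chromosome 4, the 5 windows of 100 kb with most peaks and the 5 longest stretches without a peak on the large arms. Comparisons with transcription start sites, exons, introns, gene lists and base composition had also been planned. They were not run, because the only gene table at hand is of release 6 and positions were not converted between releases.

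The overlap, the permutation of medians and the recovery of score factors were tested on simulated data. When 60% of the replicate 1 peaks were planted in a second list, 60.8% were recovered as overlapped, and 0 of 20 independent lists passed the threshold. The independent lists were placed uniformly and lacked the clustering of real peaks. They do not show how often independent clustered lists would pass. The permutation test of medians called 1.67% of 60 simulations without a difference and 100% of 60 with scores raised by 15%. The recovery of score factors described in the closing section found 5 of 5 simulated factors. The simulated counts had no cutoff for calling a peak, so this does not show that the multiple chosen for real peaks is right. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.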

Results

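Binding of ORC2 was mapped along the genome of S2-DRSC cells, a male cell line derived from late Drosophila melanogaster embryos, by chromatin immunoprecipitation and sequencing (ChIP-seq). ORC2 is a subunit of the origin recognition complex, the assembly that marks sites where DNA replication can start and onto which the replicative helicase is loaded. Chromatin came from asynchronous cultures and was precipitated with a rabbit polyclonal antibody raised against the full-length protein. The series held 2 ORC2 samples from separate extractions, called replicate 1 and replicate 2 here, and 1 input DNA sample, whose reads were not analysed here. Replicate 1 had 6834 peaks and replicate 2 had 7389, with a median width of 100 bp and 102 bp. The authors' list for the whole series had 4230 peaks with a median width of 189 bp and an interquartile range of 128 to 317 bp. Read depth is unknown, because the lists give a position and a score per peak and no read counts. Nothing in the labels says that the extractions came from separate cultures, so the spread between the 2 samples may be technical. The labels name the antibody as the experimental factor and give no second condition, so the comparisons were between replicates, between chromosomes and along the chromosome arms.

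The first question was how far the 2 samples located ORC2 at the same places. In replicate 1, 4296 of 6834 peaks (62.9%, exact binomial 95% interval 61.7 to 64.0%) touched a replicate 2 peak by at least 1 bp. In replicate 2, 4285 of 7389 peaks (58.0%, interval 56.9 to 59.1%) touched a replicate 1 peak. Sliding one list along each chromosome by a random distance left 1.76% ± 0.198 (SD, n = 1000 shifts) of the replicate 1 peaks touching, and the highest shift gave 3.54%, so that the observed share was 35.8-fold above placement by chance (one-sided permutation p = 0.000999, the smallest that 1000 shifts can give). A further 2538 peaks of replicate 1 and 3104 of replicate 2 had no touching partner. The shifts tested random placement only. The series has 1 input sample, and if both lists were called against the same control, that alone could put peaks at the same places. Every one of the 4230 whole-series peaks spanned exactly the outer edges of the peaks that touched in both replicates, and all of the touching peaks were in it. The list is therefore the set of peaks called in both samples by construction, and its share found in both (4230 of 4230) is not a separate measurement.

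Width separated the sites found in both samples from those found once. Of the replicate 1 peaks narrower than 20 bp, 14.6% were overlapped by the other sample, against 47.8% of those of 50 to 99 bp, 85.0% of those of at least 100 bp and under 200 bp, and 96.3% of those of 400 bp or more. In replicate 2 these shares were 12.7%, 41.6%, 77.1% and 95.4%. The median width was 143 bp for the shared and 51 bp for the unshared peaks of replicate 1, and 156 bp and 56 bp in replicate 2. The score, a number per peak written by the authors' peak caller, separated them much less. Shared peaks had a median score of 3.55 and unshared peaks 3.20 in replicate 1, a difference of 0.348, and the medians were 3.81 and 3.31 in replicate 2, a difference of 0.492 (two-sided permutation tests with 100000 resamples, 1 per replicate, p = 1e-05 in each, the smallest they can give). Peaks lie in clusters and are not independent, and both tests rest on the same overlaps, so these permutation p-values are likely too small. The mean scores were closer, at 4.37 for shared and 4.32 for unshared peaks in replicate 2. With peaks matched by centres within 500 bp these means were 4.322 and 4.403, opposite in sign to the medians. The shares by width were drawn up after the data were examined, and they are not corrected for the higher chance of a wide interval to touch another.

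**Figure D1:**
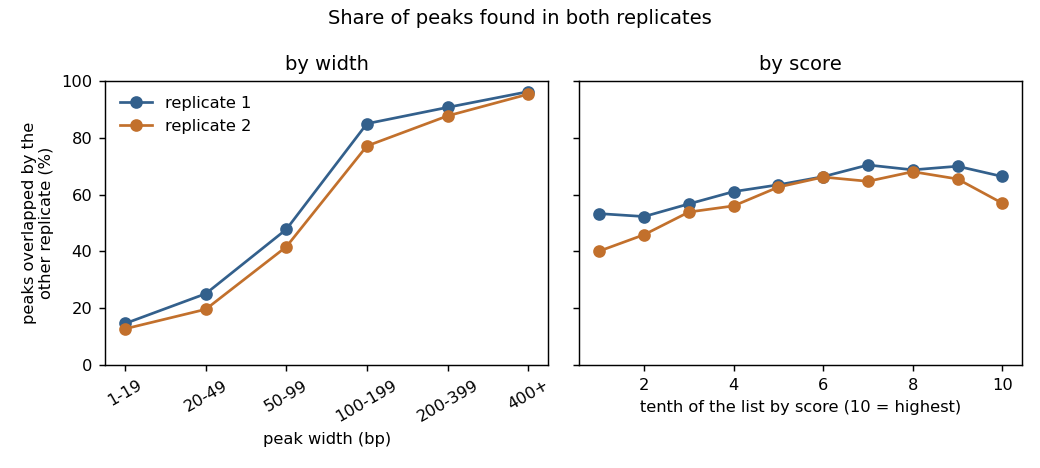
Share of ORC2 peaks overlapped by at least 1 bp by a peak of the other replicate (vertical axis, percent), by peak width in bp (left) and by score, with each list split into 10 groups of equal size (right), with 1 line per replicate. The share climbs from 14.6% and 12.7% in the narrowest class to 96.3% and 95.4% in the widest, whereas the group with the highest scores has 66.4% and 57.0%.

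The scores of peaks called in both samples were compared. For 4115 peaks that overlapped one to one, Spearman's rho was 0.780 (95% interval from resampling the peaks, 0.766 to 0.793) and Pearson's r of the log10 scores was 0.822 (0.810 to 0.833). These correlations are across peaks, which are not independent replicates. The series has 1 input sample, and if both lists were scored against the same control, that alone would correlate the scores; no value without it was computed. Replicate 2 scored slightly higher, with a median difference of 0.10 on the log2 scale and an SD of 0.35 over the pairs. The scores were within 1.5-fold of each other for 3654 pairs (88.8%) and more than 2-fold apart for 40 pairs (0.972%). Scores span a narrow range, with interquartile ranges of 2.84 to 4.58 and 2.99 to 4.99 for all shared peaks of replicates 1 and 2. Unrelated pairs would thus often be within 1.5-fold too, and their share was not computed. For each of these 4115 peaks, the score of the whole-series list was the mean of the 2 replicate scores to within 1e-05.

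**Figure D2:**
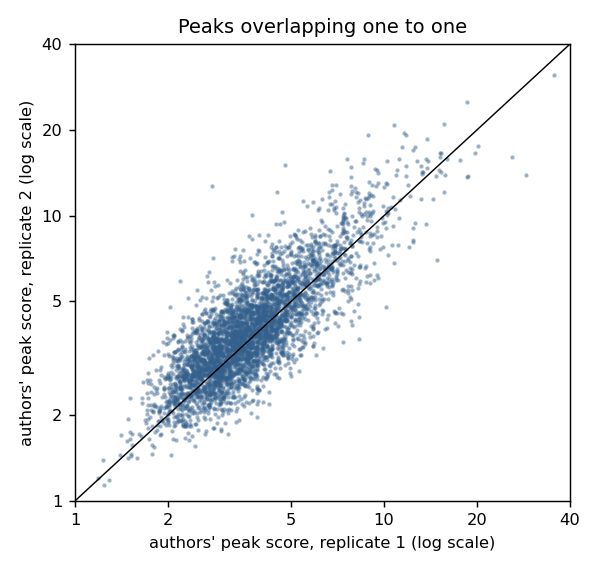
Authors' score of each of the 4115 peaks that overlapped one to one, in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), with the line of equality. The points follow the line, with a Spearman's rho of 0.780 and 88.8% of the pairs within 1.5-fold. The share for unrelated pairs was not computed.

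The 12 whole-series sites with the highest score on the large arms and chromosome 4 were between 103 and 309 bp wide and lay on all 5 large arms. All coordinates are those of FlyBase release 5 as given in the files, and genes at these sites were not identified because no gene annotation of that release was used here. The highest was at 2R, 13033255 to 13033357, with a score of 33.3 (35.4 in replicate 1 and 31.1 in replicate 2), and its nearest neighbour lay 47050 bp away. It ranked 1 in replicate 1 and 11 in replicate 2. The 12 sites ranked between 1 and 51 in replicate 1 and between 11 and 125 in replicate 2, where 3 were outside the first 100 (at 3R, 3172312, at 2L, 7856492, and at 3L, 3789272). The next were at X, 16692339 to 16692466, with a score of 21.8 (18.6 and 25.1), and at 3R, 3172312 to 3172433, with a score of 21.4, where the replicates were furthest apart among these 12 sites (28.8 and 13.9). A peak at 3L, 19900561 to 19900674, scored 18.8 (20.2 and 17.5). A second site on 2R, at 13339748 to 13339851, scored 18.3 (15.6 and 20.9), and a second site on 3L, at 19476239 to 19476346, scored 18.1 (19.7 and 16.6). The peaks at X, 4803939 to 4804060, and X, 7954962 to 7955270, scored 16.6 (17.6 and 15.6) and 16.0 (15.3 and 16.6), and each had another whole-series peak within 554 bp and 218 bp. On 2L, the peak at 7856492 to 7856664 scored 16.2 (18.7 and 13.8). On 3R, those at 20105180 to 20105329 and 7947018 to 7947169 scored 16.2 (13.8 and 18.6) and 15.9 (16.0 and 15.8). On 3L, the peak at 3789272 to 3789428 scored 16.1 (18.5 and 13.6). Of the 100 peaks with the highest score in each replicate's own list, on all sequences, 55 in replicate 1 and 36 in replicate 2 were overlapped by the other sample, and 61 and 42 with the large arms only.

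The second question was how ORC2 sites were distributed between the chromosomes. S2-DRSC cells are male, and in male flies transcription of the X is raised by dosage compensation. The X had 743 whole-series peaks, or 33.2 per Mb, and the large autosome arms had between 32.9 per Mb (2L, 755 peaks) and 38.3 per Mb (3R, 1068 peaks), with 33.2 per Mb on 3L (815 peaks) and 37.0 per Mb on 2R (781 peaks). Lengths were taken up to the last peak of any list on each arm. In windows of 100 kb, the X had 33.2 ± 35.3 peaks per Mb (SD, n = 224 windows) and the autosome arms 35.4 ± 33.8 (n = 963 windows). The X was 2.27 per Mb lower (difference -2.27, 95% interval -7.05 to 2.90, two-sided permutation p = 0.372), which does not exclude a difference of either sign within that interval. Among the 50% of whole-series peaks with the highest scores the X was higher instead, by 3.03 per Mb (two-sided permutation p = 0.0303), and with replicate 2 alone by 0.527 per Mb (permutation p = 0.891). Neighbouring windows are not independent, so these p-values are too small, and the copy number of the arms in these cells was not corrected for.

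All sequences in the lists outside the large arms had fewer whole-series ORC2 sites per Mb than those arms. Chromosome 4, the small dot chromosome that is largely heterochromatic, had 30 whole-series peaks over 1.23 Mb (24.3 per Mb), against 75 peaks in replicate 1 (60.8 per Mb) and 72 in replicate 2 (58.3 per Mb). The assembled heterochromatin of 2R had 5 whole-series peaks over 3.23 Mb (1.55 per Mb), that of 3L had 7 (2.75 per Mb) and that of 3R had 7 (2.78 per Mb), while that of 2L had 1 (3.84 per Mb) and that of X had 2 over 0.0849 Mb (23.6 per Mb). Lengths here end at the last peak of any list, so the densities are upper limits, above all on sequences with few peaks, such as the heterochromatin of X and 2L. The unplaced sequences, named U, had 16 peaks over 8.93 Mb (1.79 per Mb), and these were wide, with a median of 410.5 bp, and low in score, with a median of 2.63 against 3.49 to 4.04 on the large arms. In replicates 1 and 2 the U peaks had median widths of 96 and 100 bp and median scores of 4.19 and 3.28. Chromosome 4 and the heterochromatin sequences had higher whole-series median scores, from 4.21 to 9.12, over 1 to 30 peaks each. These sequences are rich in repeats, where short reads often cannot be placed, and their density was described without a test. The single lists were denser there, with 13.6 and 14.2 peaks per Mb in replicates 1 and 2 on the heterochromatin of 2R, 17.7 and 16.9 on that of 3L, 9.53 and 10.7 on that of 3R, 19.2 in each on that of 2L, 47.1 and 58.9 on that of X and 9.74 and 8.51 on U, against 51.8 to 63.7 on the large arms, so that the whole-series densities also reflect how often peaks were found in both.

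The third question was whether sites fell evenly along an arm. They did not. On the 5 large arms the median distance between neighbouring whole-series peaks was 9715 bp, against 19734 bp when the same peaks were placed uniformly at random within each arm (SD 311, lowest of 1000 placements 18777; two-sided permutation p = 0.002, the smallest possible). The variance of the count per 100 kb window was 3.31 times its mean, against 1.01 in the random placements, of which the highest reached 1.17 (permutation p = 0.002). Of 1187 windows, 230 (19.4%) had no peak, and 63 (5.31%) had 10 or more and together held 808 of the peaks (19.4%). Of the distances between neighbours, 618 (14.9%) were under 1 kb. With peaks less than 1 kb apart merged, the variance was 2.27 times the mean. The random placements used every base of an arm, also where short reads cannot be placed. The test therefore covers the called peaks, and cannot tell uneven binding of ORC2 from uneven placement of reads.

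The window with most ORC2 sites was on 3R, from 12000000 to 12099999, with 25 whole-series peaks (29 in replicate 1 and 31 in replicate 2). It was followed by X, 12600000 to 12699999, with 22 peaks (29 and 28), 3R, 17400000 to 17499999, with 21 (26 and 31), 2R, 9800000 to 9899999, with 19 (24 and 24), and 3R, 25600000 to 25699999, with 18 (27 and 32). The median score in these windows lay between 2.74 on 3R at 25600000 and 4.31 on 2R at 9800000. Of the 5 longest stretches without a whole-series peak, 4 lay within the 2 Mb of an arm next to its centromere. On 2R and 3L these were 2R, 716742 to 1540663 (824 kb), 3L, 23251936 to 24021344 (769 kb), and 3L, 24021627 to 24529157 (508 kb). Each replicate alone had peaks in those 3, with 7 and 14 in the first, 10 and 16 in the second, and 9 and 6 in the third. On the X, the stretch from 21245382 to 21857549 (612 kb), the other of the 4, had no peak in replicate 1 and 1 in replicate 2. The stretch at X, 14105547 to 14547787 (442 kb), lay in the middle of the arm and had 4 and 6. How much of these stretches short reads can cover was not examined.

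**Figure D3:**
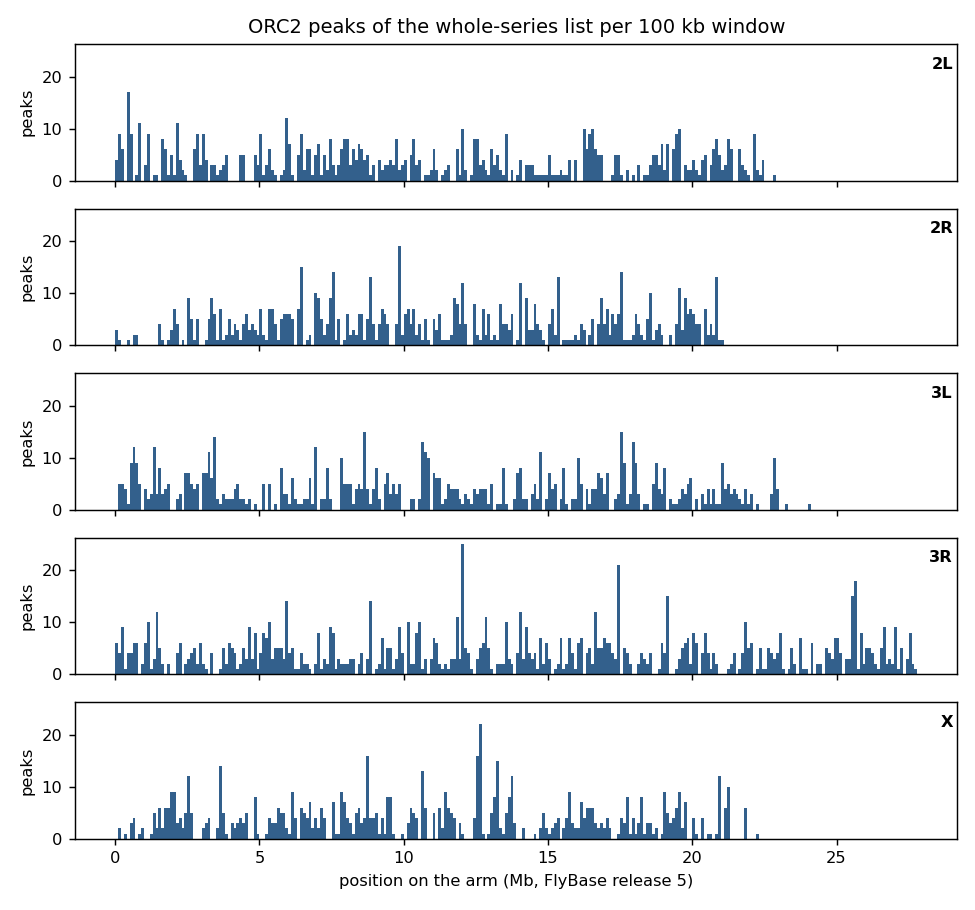
Number of whole-series ORC2 peaks (vertical axis) in consecutive 100 kb windows along each of the 5 large arms (horizontal axis, Mb, FlyBase release 5). Counts range from 0, in 230 windows, to 25 on 3R at 12000000, and the centromeric ends of 2R (left end) and 3L (right end) hold few peaks.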

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

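The overlap of the replicates, the clustering of sites and the higher median score of shared peaks kept their direction and their side of the threshold under all alternatives run for them. The share of replicate 1 peaks overlapped ranged from 43.9% (at least 50% of both peaks) to 70.2% (centres within 500 bp), and that of replicate 2 from 40.6% to 66.5%. The variance over the mean of window counts ranged from 2.05 (the 50% of peaks with the highest scores) to 4.51 (replicate 2 alone). The X minus autosome density of -2.27 peaks per Mb changed sign to 3.03 with the 50% of peaks with the highest scores (permutation p = 0.0303); it was -4.07 with replicate 1 alone and 0.527 with replicate 2 alone. Median scores were higher on the X (4.04 against 3.49 to 3.77 on the other large arms), so a filter on score keeps more of its peaks; for the single replicates the cause was not tested. Requiring at least 50% of the whole-series peak to be covered by each replicate lowered the share found in both from 100% to 74.2%, since the list merges both extents. Pairing peaks by centres within 500 bp moved Spearman's rho to 0.757 and Pearson's r to 0.794, and the cause was not tested. No paired analysis was possible because there is 1 group of ORC2 samples and the only other sample, the input, was not analysed here. The alternatives planned for start sites, gene features, gene lists and base composition were not run for want of an annotation and genome of release 5. Without read counts, the peaks found once cannot be weighed by depth.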

Other observations

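The values by kind of sequence, by arm end and by width in this part, both tests on the X, the other multiples of its factor, the tests of the 100 highest scores and the comparison of numerators with denominators were chosen after the data had been seen. Peaks on the heterochromatic and unplaced sequences were found in both samples less often than peaks on the large arms. On the sequences labelled Het and U together, 38 of 209 replicate 1 peaks (18.2%, exact binomial 95% interval 13.2 to 24.1%) and 38 of 202 replicate 2 peaks (18.8%, 13.7 to 24.9%) were overlapped by the other sample, against 64.5% and 59.3% on the large arms (two-sided Fisher's exact tests, p = 1.1e-41 and 4.6e-31, Benjamini-Hochberg adjusted over 4 tests 4.4e-41 and 9.1e-31). Het and U peaks were narrower, with medians of 76 bp and 75 bp against 100 bp and 103 bp on the large arms; at the large arms' shares for 6 classes of width, 53.4% and 48.8% of them would be shared. On chromosome 4 the shares were 40% (30 of 75, interval 28.85 to 51.96%) and 41.7% (30 of 72, 30.15 to 53.89%). Fisher's exact p was 2.6e-05 and 0.00354 (adjusted 3.5e-05 and 0.00354), without regard to width. At the large arms' shares by width, 63.3% and 53.3% would be shared. The replicate 2 interval includes that value, so in replicate 2 a lower share beyond width is not shown. Peaks lie in clusters and are not independent, and the tests of both replicates count the same overlaps, so these Fisher p-values are likely too small. Along the large arms, the 2 Mb next to the centromere had 9.0 whole-series peaks per Mb on 2R, 10 on 3L, 19 on X and 24.5 on 2L, against 39.5, 34.1, 35.6 and 32.4 in the middle of those arms, whereas on 3R it had 41.5 against 38.2. In the single lists the gap was smaller in proportion on 3 of these arms, with 19 and 33.5 per Mb in replicates 1 and 2 next to the centromere of 2R against 61.0 and 67.3 in its middle, 25 and 28 against 55.8 and 58.0 on 3L, and 46 and 53 against 53.8 and 55.8 on 2L, so that the whole-series values there also reflect how often peaks were found in both. On the X the single lists had 30 and 31 against 55.3 and 64.6. How much of the 2 Mb next to a centromere short reads can cover was not examined. The distal 2 Mb had 45.5 on 2L, 43.5 on 2R and 47 on 3L, but 36 on 3R and 25 on X.

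Of the 5 widest whole-series sites, 3 lay close together on 3L, at 634449 to 637277 (2829 bp, score 1.19), 639237 to 641716 (2480 bp, score 2.204) and 651807 to 656652 (4846 bp, score 1.19). The first and the last of these had the lowest scores of all 4230 peaks. The widest single peaks in these 3 were 1835, 1714 and 1976 bp in replicate 1 and 2829, 2480 and 4846 bp in replicate 2. The other wide entries were at 2L, 3057908 to 3060557 (2650 bp, score 2.5), and 2L, 19574963 to 19577032 (2070 bp, score 5.69). The former merged 3 peaks of each replicate, the widest of 926 bp in replicate 1 and 904 bp in replicate 2. The latter was called as a single peak of 2070 bp in replicate 1 and 2014 bp in replicate 2.

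The scores had a numerical structure. On each large arm, 96.7 to 99.3% of the scores equalled a ratio of 2 whole numbers with a denominator of at most 120, times 1 factor for that arm and replicate, within the rounding of the printed digits. With 50 wrong factors per arm and replicate the mean share was 2.199 to 4.44% and the highest 37.7%, for the X in replicate 2. The factors were 1.96 (2L), 2.15 (2R), 1.93 (3L), 1.94 (3R) and 1.96 (X) in replicate 1, and 1.75, 1.90, 1.66, 1.73 and 1.70 in replicate 2. Simple multiples of a factor give nearly the same share. The criterion between them was how close the shares divisible by small primes came to those of arbitrary whole-number ratios in lowest terms. With the multiples chosen, 30.1 to 33.9% of numerators and 29.8 to 35.6% of denominators were even, shares that the criterion itself selected for. This criterion was settled as the last of 3 that were run, after the outcomes under the earlier criteria had been seen. Those were dropped because they gave unequal multiples between arms. The 20% of peaks on the large arms with the largest recovered numerators were shared in 97.3% (replicate 1) and 94.4% (replicate 2), and the 20% with the largest recovered denominators in 90.4% and 85.6%, against 71.5% and 63.2% for the 20% with the highest scores. Below, the whole numbers are read as reads of the ChIP and of a control, which the files do not state, and they are known only up to a cancelled common divisor.

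Of the replicate 1 peaks, 37.1% were called in that replicate only. If the caller had placed the same sites slightly apart, at least 50% of them should have a partner close by. Only 639 of 2538 (25.2%) lay within 500 bp of a replicate 2 peak, above all 1000 shifts (mean 4.90%, highest 9.02%). Near misses within 500 bp can thus account for at most this part. The shifts also separate clusters common to both lists, and the close peak could itself touch another replicate 1 peak. The excess over the shifts therefore does not show that these were the same sites. Widening each interval to at least 200 bp raised the overlapped share of replicate 1 from 62.9% to 65.8%, which argues against narrow intervals missing each other as the main cause. A difference in depth stays open, as depth is unknown. No biological explanation was tested, since both samples are of 1 group.

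In replicate 2 the peaks with the 100 highest scores were shared less often than the others, with 36 of 100 (exact binomial 95% interval 26.6 to 46.2%) against 58.3% (two-sided Fisher's exact p = 9.1e-06, Benjamini-Hochberg adjusted over 4 tests 3.6e-05), and on the large arms 42 of 100 (32.2 to 52.3%) against 59.5% (Fisher's exact p = 0.000642, adjusted 0.00128). Peaks are not independent replicates, so these p-values are likely too small. In replicate 1 no difference passed the threshold, with 55 of 100 against 63.0% (Fisher's exact p = 0.117, adjusted 0.157) and on the large arms 61 of 100 against 64.6% (p = 0.462, adjusted 0.462). A candidate explanation is a small number of control reads under such peaks; among these 100 of replicate 2 on the large arms, of the peaks with a recovered ratio, the median lowest-terms denominator was 1.0 for 49 unshared and 6.0 for 32 shared peaks, a ratio of 0.167 (95% interval 0.118 to 0.50). The numerators were lower as well, at 17 against 57.5 (ratio 0.296), and the denominator ratio over the numerator ratio was 0.564 (0.483 to 1.37), so that few control reads and few reads of both kinds cannot be told apart, since peaks chosen for a high ratio have both numbers low together. A test first set on the 10% of replicate 2 peaks on the large arms with the highest scores gave a ratio of 0.353. Of those with a recovered ratio, 57.8% were shared, against 59.3% of all peaks on the large arms with or without one, so it does not bear on the pattern. No biological explanation was tested.

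Scores were higher on the X, with a median of 3.91 against 3.31 on the autosome arms in replicate 1 (ratio 1.18, 95% interval 1.16 to 1.24) and 3.97 against 3.55 in replicate 2 (ratio 1.12, 1.09 to 1.16; two-sided permutation p = 1e-04 in each, the smallest that 10000 resamples give, over peaks, which are not replicates). Without the factor per chromosome the ratio was 1.20 in replicate 1 and 1.17 in replicate 2, but this rests on the criterion for the factor: under the first criterion run the replicate 1 ratio was below 1, and all 11 simple multiples of the X factor tried gave whole ratios for at least 90% of the X scores, with ratios from 0.30 to 4.8. Under the criterion used, denominators were lower on X, with medians of 9.5 against 15 and 9.0 against 15. A peak with fewer control reads may need a higher ratio to be called. Numerators were lower on X as well, with medians of 19 against 24 and 21 against 29. Under that criterion the lower numbers were thus not particular to the control, and the copy number of the arms was not corrected for. Matched on all denominators, the test as first set, the ratio was 1.21 (95% interval 1.16 to 1.26) in replicate 1. In replicate 2 it was 1.054 (1.02 to 1.13), and 1017 and 1161 X peaks were used. Both intervals lay above 1, which went against fewer control reads as the full explanation. A small lowest-terms denominator does not fix the control count, however, so this test cannot decide. Matching was limited to denominators of 20 or more after the replicate 1 value was seen, because less has cancelled there. The ratio was then 1.047 (0.977 to 1.11) in replicate 1 and 1.032 (0.970 to 1.10) in replicate 2. These last values rest on only 236 of 1160 and 262 of 1351 X peaks. Scaling per chromosome, fewer control reads on the X, fewer reads of both kinds there and a stronger enrichment of ORC2 on the X of male cells cannot be told apart. The multiple of the factor is not fixed by the scores. In replicate 1, matching on all denominators and on those of 20 or more gave different ratios, and the intervals of the latter are wide. A stronger enrichment was not tested.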
